A study of Homo sapiens with 36 samples.

How the data were processed

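RNA was sequenced from 36 libraries of cancer cell lines after poly-T selection of mRNA and preparation with the NEB Next Ultra RNA kit, per the labels. The submitters' processing notes name FastQC for read quality, Trimmomatic for trimming and STAR for alignment to hg38. Their versions, the counting tool, the gene annotation, the test behind the fold changes, any shrinkage of them and any filter on genes are not given in the sources used here. The authors then deposited 1 table of 4 comparisons over 11828 genes. Per the file headers, its fold changes are log2 values of the group named first over the group named second. Per the file headers, its other columns are a p-value and an adjusted p-value (padj) made by the authors. Dividing out the Benjamini-Hochberg ranks gave 15844, 14805, 16484 and 12062 genes behind the adjusted p-values of 6-thio-dG in A375, 6-thio-dG in HCC827, the combination in A375 and the combination in HCC827, so the table holds a subset of the genes the authors tested. The ratios behind these numbers were whole within a relative 1e-06 for 99%, 93%, 99.3% and 72.5% of the genes checked. The p-value is listed as 0 for 7, 0, 16 and 0 genes in that order.

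The design fixed before the data were examined assumed counts or normalised values per library and a model fitted to them, and the table holds log2 fold changes and p-values instead. The authors' own tests were therefore used as the starting point. The gene lists and the rule for named genes were fixed then too. The tests of SUCLG2 against span, exonic length and GC content over all 4 comparisons, and of chromosome ends, were fixed before their results were seen. The time course, the targeted drug against control, the combination against control or against 6-thio-dG, and osimertinib in both experiments were not analysed here. The depth per library is unknown, and the precision of a value is known only through the standard error that it and its p-value imply.

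The 4 comparisons were read as sharing no libraries. This reading takes "RNA" in the header as the control and "TKI1" as the targeted-drug arm, neither of which the header states. A gene was called at the authors' adjusted p under 0.05. Each p-value was turned into a two-sided normal z with the sign of the fold change, and the implied standard error is the size of the fold change divided by that of z. Differences between 2 comparisons were tested with a two-sided z test on these errors and adjusted by Benjamini-Hochberg over the genes in each of 4 families. Genes with a p-value listed as 0 were left out of those tests and entered list tests at a p-value near the smallest that the software holds.

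Of 33 gene lists, 31 had at least 5 measured members and were tested with the competitive camera test for preranked statistics (cameraPR in limma 3.58.1 under R 4.3.3) on the signed z, with a preset correlation of 0.01. The test is two-sided and was adjusted by Benjamini-Hochberg over the lists in each of 8 families, 4 of comparisons and 4 of differences. An estimated correlation needs values per library and could not be had, so a preset correlation of 0.05 was tried in its place. Counts within a list were given over all genes and adjusted over the list alone. Overlaps of called genes were tested by two-sided Fisher's exact tests, 16 in all, adjusted together. Genes are not independent replicates, so p-values over genes may be read only as a ranking of overlaps and lists.

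Gene names were matched to GENCODE release 29, which gave 11795 of 11828 genes (99.7%) a single match, 99.9% of these protein coding. The annotation gave each gene's position, span, merged exonic length and GC content. The trend of fold change on GC content was removed with a lowess curve over 0.3 of the genes, and the tests were repeated with the implied standard errors. A further alternative removed the trends on GC content, exonic length and span together. Other alternatives were an adjusted p of 0.01, a change of at least 2-fold, adjustment recomputed over the table's genes, the p-value read as a t test with 4 degrees of freedom, and ranks in place of z. All of these alternatives were chosen after seeing the data.

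Named genes follow a rule: SUCLG2, SUCLG1, SUCLA2 and TERT always; the 8 largest rises and the 8 largest falls among called genes (5 and 5 for differences); and up to 4 members with the smallest p-values of each list that passed, and always of ERK pathway output, mitosis, the TCA cycle, telomerase and telomere binding, p53 targets and interferon stimulated genes. The parts of the rule that ask for an expression minimum and for the same direction in every library could not be applied. Names of noncoding or unplaced loci, XIST and Y-linked genes were left out, and some genes that the rule selects are not reported here. Fold changes of single genes as deposited are copied from the authors' table, and those with a trend removed were computed from them.

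The steps were tested on simulated data with the table's own standard errors. A rising linear GC trend was imposed, the same in all 4 comparisons, so it is not the trend of any of them. The data simulated for the difference test held no GC trend. Changes were planted in a small set of genes drawn without regard to GC content, far fewer than passed in the data. After the GC trend was removed, simulated changes of 1 on the log2 scale were recovered at 71% for 6-thio-dG in A375, 75% for 6-thio-dG in HCC827, 79% for the combination in A375 and 86% for the combination in HCC827, and changes of 2 at 94%, 98%, 90% and 98%. The difference test recovered changes of 1 at 56%, 39%, 63% and 58%, and changes of 2 at 89%, 92%, 85% and 88%. Unchanged genes were called at 26.9%, 16.7%, 26.4% and 26.9% before the imposed GC trend was removed and at 0.0604%, 0.121%, 0.0690% and 0.129% after. Of 4 shifted lists 3 were called in A375 after 6-thio-dG and 4 in each other comparison, and 0 of 23 unshifted lists were called. The list statistics were drawn independently for each gene and not from the table's errors. They therefore do not show how often lists of correlated genes are called falsely. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.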

Results

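RNA sequencing of mRNA selected by its poly(A) tail measured transcript levels in 36 libraries from cancer cell lines. The comparisons reported here come from a mechanism experiment of 16 libraries. It used A375, a BRAF-mutant melanoma line, and HCC827, an EGFR-mutant lung adenocarcinoma line, with 4 treatments per line, 2 libraries per treatment and line, and 3 days of treatment. The treatments were a control, a targeted drug (the BRAF inhibitor PLX4720 in A375, the EGFR inhibitor osimertinib in HCC827), 6-thio-dG (a modified guanine nucleoside that telomerase can add to telomeres), and the targeted drug together with 6-thio-dG, called the combination. The other 20 libraries form a time course of 4 lines in 5 states with 1 library each, and were not analysed here. The values come from the authors' deposited table, which holds 11828 genes and 4 comparisons, each with a log2 fold change, a p-value and an adjusted p-value. It holds 0 columns of values per library, so no spread between replicates can be given, and the error quoted is the standard error that each fold change and its p-value imply. The depth of the libraries is unknown. The table's header names the arm that 6-thio-dG was compared with "RNA", a name no library title carries. It was read as the control and is called the reference. The header of the combination comparisons names the other arm "TKI1", and whether that means the targeted-drug group or a single library of it is not stated.

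Of the 11828 genes, 7690 (65.0%) passed an adjusted p of 0.05 for 6-thio-dG in A375, with 3707 that rose and 3983 that fell, and 3455 (29.2%) passed for 6-thio-dG in HCC827, with 1749 that rose and 1706 that fell. The combination against the targeted drug gave 7153 genes (60.5%) in A375, with 3685 that rose and 3468 that fell, and 4167 (35.2%) in HCC827, with 2052 that rose and 2115 that fell. Changes of at least 2-fold numbered 3668, 998, 3202 and 273 in the same order, and of the 273 in the HCC827 combination 19 rose and 254 fell. In every comparison the fold change moved with the GC content of the transcript. Across genes, which are not independent replicates, Spearman's rho was -0.38 for 6-thio-dG in A375, 0.22 for 6-thio-dG in HCC827, -0.25 for the combination in A375 and 0.73 for the combination in HCC827. Once this trend was removed 910 genes passed in the HCC827 combination, 59.3% of them rises, against 49.2% rises among the 4167 that passed as deposited.

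**Figure D1:**
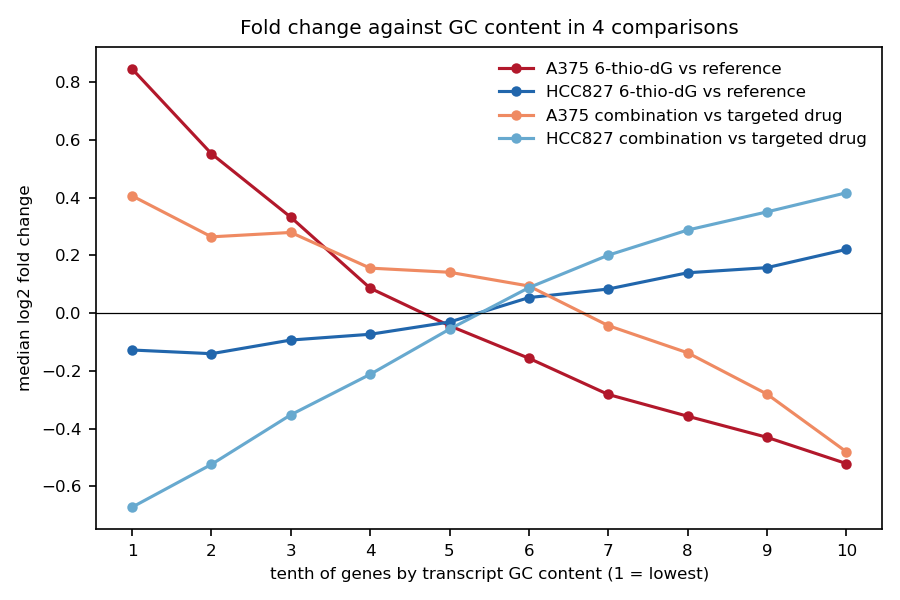
Median log2 fold change (vertical axis) of genes in 10 groups of equal size by transcript GC content (horizontal axis), 1 line per comparison. The median went from -0.67 in the lowest group to 0.42 in the highest for the HCC827 combination, and from 0.85 to -0.52 for 6-thio-dG in A375.

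6-thio-dG alone in A375 addresses what the nucleoside does to melanoma cells without the BRAF inhibitor. Cell-cycle genes fell as whole groups: all 29 mitosis genes measured fell (median log2 fold change -3.54, adjusted p = 9.76e-71 for the list), and all 37 DNA replication genes fell (median -2.45, adjusted p = 6.79e-47). The authors' deposited table gives log2 fold changes of -5.97 for PLK1, a mitotic kinase, -5.16 for FOXM1, a transcription factor of mitotic genes, -4.13 for RRM2, a subunit of ribonucleotide reductase, and -3.97 for MCM5, a subunit of the replicative helicase. Targets of p53 rose: 26 of 27 rose and 1 fell (median 1.31, adjusted p = 1.0e-15). GDF15, a secreted stress cytokine, stood at 4.43, GADD45A, a growth-arrest gene, at 3.45, and CDKN1A, an inhibitor of cyclin-dependent kinases, at 2.51 (adjusted p = 1.1e-50) in the authors' deposited table. Of 31 genes of homologous recombination and the Fanconi pathway, which repair double-strand breaks and crosslinks, 21 fell and 3 rose (median -1.37, adjusted p = 1.2e-06), with FANCI at -3.38 in the authors' deposited table.

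Matrix and dedifferentiation genes also fell in A375 after 6-thio-dG. Of 14 mesenchymal genes 10 fell and 2 rose (median -1.34, adjusted p = 0.0023), and of 14 neural crest and dedifferentiated melanoma genes 11 fell and 2 rose (median -1.02, adjusted p = 0.00027). COL6A1, a chain of collagen VI, was at -3.47, TNC, the matrix protein tenascin C, at -3.69 and ACTA2, smooth muscle actin, at 2.88 in the authors' deposited table. Of 23 glycolysis genes 17 fell and 3 rose (median -0.87, adjusted p = 0.0092), of 26 TCA cycle genes 17 fell and 2 rose (median -0.50, adjusted p = 0.044), and of 22 antigen presentation genes 12 fell and 4 rose (median -0.46, adjusted p = 0.048). Citrate synthase (CS) was at -1.31, the mitochondrial isocitrate dehydrogenase IDH2 at -1.98, enolase (ENO1) at -1.76 and HLA-DRA, an MHC class II chain, at -2.28 in the authors' deposited table. After removal of the GC trend the list tests gave adjusted p = 0.10 for glycolysis and 0.14 for antigen presentation. With a preset correlation of 0.05 they gave adjusted p = 0.084 for glycolysis, 0.19 for the TCA cycle and 0.19 for antigen presentation.

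Several lists chosen for this treatment passed no list test in A375 after 6-thio-dG. Since 65.0% of all genes passed in this comparison, their counts of changed members are to be read against that share. The telomerase and telomere binding list had 9 of 22 genes that fell and 4 that rose (median -0.17, adjusted p = 0.33), with RTEL1, a telomere helicase, at -3.98 and DKC1, the dyskerin of the telomerase complex, at -1.22 in the authors' deposited table. TERT, the catalytic subunit, is not analysed here. The ERK pathway output list had 16 of 24 that fell and 7 that rose (median -0.56, adjusted p = 0.14), with ETV4 at -2.16, FOSL1 at -2.13 and EGR1, an immediate early factor, at 2.82 in the authors' deposited table. The interferon stimulated list had 12 of 32 that rose and 4 that fell (median 0.36, adjusted p = 0.28), with SAMD9 at 3.55 and OAS3 at -2.28 in the authors' deposited table. Adjusted over the list alone, the fallen genes numbered 29 for mitosis, 37 for DNA replication and 21 for homologous recombination. On the same basis 26 of the p53 targets rose, 3 TCA cycle genes rose, and 10 telomerase and telomere binding genes fell. Markers of another cell type were also counted: of 22 epithelial genes 5 fell and 2 rose (median 0.14, mean 0.65, adjusted p = 0.93), with the list test's own direction negative. Some of the largest rises carried readthrough names, such as PEDS1-UBE2V1 at 24.09 in the authors' deposited table, whose exons overlap those of neighbouring genes.

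**Figure D2:**
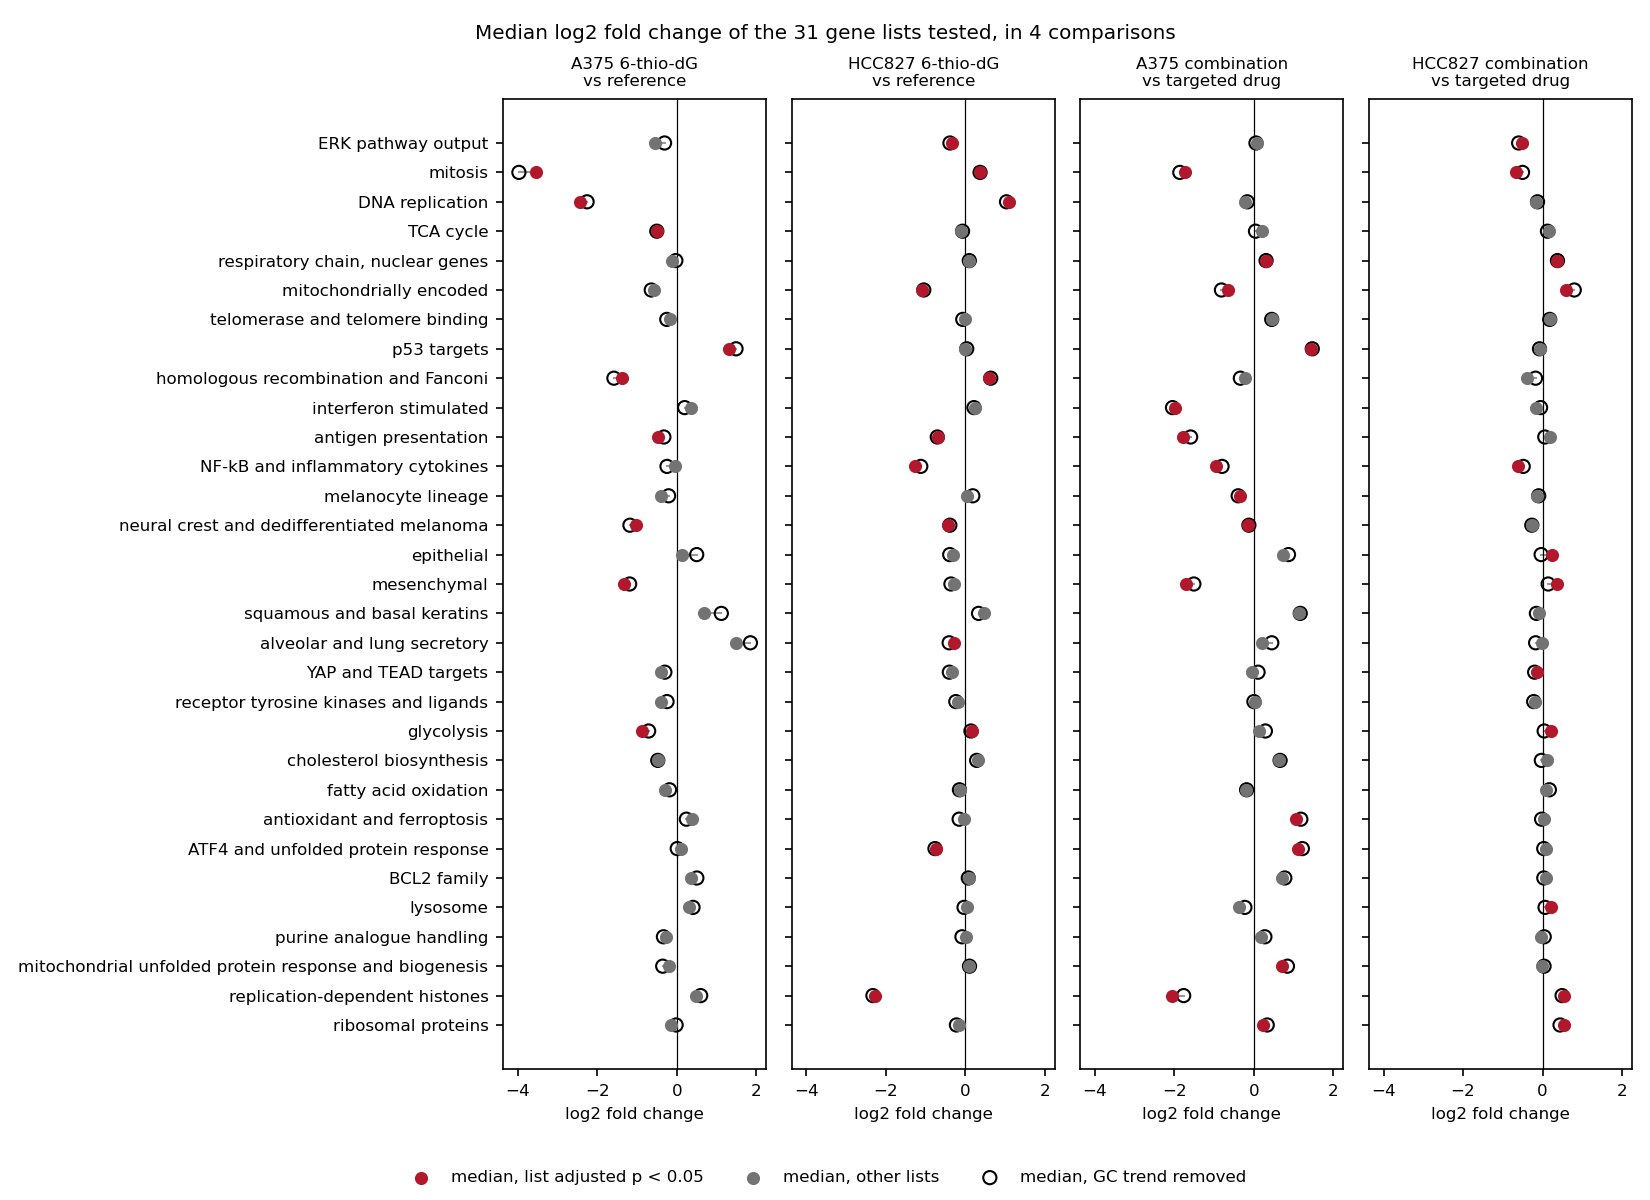
Median log2 fold change (horizontal axis) of the 31 gene lists tested (vertical axis) in the 4 comparisons; filled red points passed the list test, grey points did not, and open circles give the median with the GC trend removed. Mitosis stood at -3.54 in A375 and 0.36 in HCC827 after 6-thio-dG.

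6-thio-dG alone in HCC827 asks the same of lung adenocarcinoma cells without osimertinib. DNA replication genes rose: 34 of 37 rose and 0 fell (median 1.11, adjusted p = 4.7e-28), and 11 of 29 mitosis genes rose with 0 that fell (median 0.36, adjusted p = 0.0025). CCNE2, a cyclin of the G1/S transition, was at 3.33 (adjusted p = 1.7e-23), E2F1, a transcription factor of S-phase genes, at 1.95, CDT1, a replication licensing factor, at 1.86 and CDC20, an activator of the anaphase-promoting complex, at 1.19 in the authors' deposited table. Of 31 homologous recombination and Fanconi genes 17 rose and 2 fell (median 0.60, adjusted p = 8.9e-06), with CLSPN, a replication checkpoint mediator, at 2.20 in the authors' deposited table. Replication-dependent histone genes went the other way, with 8 of 10 that fell (median -2.28, adjusted p = 5.9e-14), among them H2AC6 at -2.90 in the authors' deposited table. Most transcripts of these histone genes lack a poly(A) tail, and the libraries were made by selecting for that tail.

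Inflammatory, antigen presentation and endoplasmic reticulum stress genes fell in HCC827 after 6-thio-dG. Of 20 genes of NF-kB and inflammatory cytokines 16 fell and 0 rose (median -1.28, adjusted p = 5.5e-19), of 22 antigen presentation genes 13 fell and 1 rose (median -0.69, adjusted p = 5.5e-10), and of 28 genes of ATF4 and the unfolded protein response 17 fell and 2 rose (median -0.74, adjusted p = 3.3e-10). The chemokine CXCL1 was at -2.32, the cytokine IL1A at -2.56, CD74, the invariant chain of MHC class II, at -3.69 (adjusted p = 1.9e-68) and HSPA5, the main chaperone of the endoplasmic reticulum, at -1.66 in the authors' deposited table. All 13 mitochondrially encoded genes fell (median -1.09, adjusted p = 3.4e-09), with MT-ND4, a subunit of complex I, at -1.47 in the authors' deposited table. Smaller shares of other lists changed: 10 of 24 ERK pathway output genes fell and 3 rose (median -0.33, adjusted p = 0.0071), 6 of 14 neural crest genes fell and 2 rose (median -0.44, adjusted p = 0.015), 2 of 8 alveolar and lung secretory genes fell and 1 rose (median -0.27, adjusted p = 0.012), and 9 of 23 glycolysis genes rose and 2 fell (median 0.17, adjusted p = 0.015). The mucin MUC5B was at -3.54, LIF, a cytokine, at -1.27 and the hexokinase HK1 at 1.14 in the authors' deposited table.

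The p53 targets passed no list test in HCC827 after 6-thio-dG, with 3 of 27 that rose and 4 that fell (median -0.01, adjusted p = 0.37). GADD45A was at -1.47, GDF15 at -1.21 and POLH, a translesion polymerase, at 1.68 in the authors' deposited table. Also without a passing test were the TCA cycle (2 of 26 rose, 5 fell, adjusted p = 0.37), the telomerase and telomere binding list (3 of 22 rose, 4 fell, median -0.00012, mean 0.00086, negative in the test, adjusted p = 0.92) and the interferon stimulated list (6 of 32 rose, 1 fell, adjusted p = 0.15). Adjusted over the list alone, 35 DNA replication genes, 13 mitosis genes and 18 homologous recombination genes rose, and 14 antigen presentation genes fell while 3 rose. With a preset correlation of 0.05 the adjusted p was 0.061 for ERK pathway output, 0.063 for neural crest and 0.090 for glycolysis. On ranks in place of p-values it was 0.46 for the alveolar list, 0.13 for neural crest and 0.090 for glycolysis.

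The combination against PLX4720 in A375 addresses what 6-thio-dG adds to the BRAF inhibitor. Genes of immune recognition fell: 19 of 22 antigen presentation genes fell and 1 rose (median -1.79, adjusted p = 5.4e-22), and 28 of 32 interferon stimulated genes fell and 2 rose (median -1.99, adjusted p = 1.4e-13). HLA-DRA was at -4.62, CIITA, the transactivator of MHC class II genes, at -4.34, BST2, an antiviral tether, at -4.51 (adjusted p = 5.5e-169) and IFIT1, an antiviral RNA-binding protein, at -3.23 in the authors' deposited table. Stress genes rose: 22 of 28 ATF4 and unfolded protein response genes rose and 3 fell (median 1.11, adjusted p = 1.4e-13), 22 of 27 p53 targets rose and 1 fell (median 1.44, adjusted p = 1.4e-13), and 18 of 27 antioxidant and ferroptosis genes rose and 6 fell (median 1.06, adjusted p = 2.2e-07). GDF15 was at 6.79, DDIT3, a transcription factor of the stress response, at 5.03, ASNS, asparagine synthetase, at 3.35, CDKN1A at 2.65 (adjusted p = 2.8e-90), FTH1, the ferritin heavy chain, at 2.87 and SLC3A2, a subunit of the cystine transporter, at 3.20 in the authors' deposited table. Lists could share members: GDF15 was the highest gene of both the ATF4 and the p53 list, so their rises are not fully separate. Of 29 mitosis genes 25 fell and 1 rose (median -1.74, adjusted p = 4.9e-05), with MKI67, a proliferation marker, at -3.51 and TOP2A, topoisomerase II alpha, at -2.96 in the authors' deposited table.

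Matrix and inflammatory genes fell as well in the A375 combination. Of 14 mesenchymal genes 12 fell and 2 rose (median -1.72, adjusted p = 6.8e-10), of 20 NF-kB genes 14 fell and 1 rose (median -0.95, adjusted p = 0.00048), of 10 replication-dependent histones 8 fell (median -2.05, adjusted p = 0.0023) and of 13 mitochondrially encoded genes 10 fell (median -0.66, adjusted p = 0.021). TGFBI, a matrix protein, was at -4.56, the chemokine CCL2 at -4.73 and MT-CO3, a subunit of cytochrome c oxidase, at -1.02 in the authors' deposited table. In the melanocyte lineage list 3 of 7 fell and 1 rose (median -0.36, adjusted p = 0.00047), with MITF, the lineage transcription factor, at -1.95 and ERBB3, a receptor kinase, at -4.50 in the authors' deposited table. In the neural crest list 5 of 14 fell and 4 rose (median -0.14, adjusted p = 0.036), with TNC at -6.13 and the growth factor NRG1 at 2.73 in the authors' deposited table. Of 23 genes of the mitochondrial unfolded protein response and biogenesis 15 rose and 0 fell (median 0.70, adjusted p = 0.00074), and 27 of 50 nuclear respiratory chain genes rose and 7 fell (median 0.31, adjusted p = 0.020). The mitochondrial chaperones HSPD1 and HSPA9 were at 1.28 and 1.25, and CYCS, cytochrome c, at 1.27 in the authors' deposited table. Of 38 ribosomal protein genes 19 rose and 2 fell (median 0.24, adjusted p = 0.036), with RPS24 at 0.72 in the authors' deposited table.

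Of the 31 lists tested 15 passed in the A375 combination. Among those that did not were ERK pathway output (9 of 24 rose, 7 fell, median 0.07, mean -0.19, negative in the test, adjusted p = 0.38), the TCA cycle (9 of 26 rose, 8 fell, adjusted p = 0.47), DNA replication (4 of 37 rose, 13 fell, adjusted p = 0.62) and telomerase and telomere binding (12 of 22 rose, 2 fell, median 0.46, adjusted p = 0.071). PHLDA1 was at -2.64 and ETV1 at -3.11, while IDH1, the cytosolic isocitrate dehydrogenase, was at 1.71 and GAR1, a telomerase complex protein, at 1.26 in the authors' deposited table. Adjusted over the list alone, 20 antigen presentation genes, 29 interferon stimulated genes and 26 mitosis genes fell, and 18 mitochondrial unfolded protein response genes rose. With a preset correlation of 0.05 the adjusted p was 0.18 for the respiratory chain, 0.073 for the mitochondrially encoded genes, 0.12 for neural crest and 0.20 for ribosomal proteins. On ranks it was 0.12 for the melanocyte lineage and 0.56 for neural crest. Telomerase and telomere binding passed on ranks, upward, and lysosome genes downward (adjusted p = 0.0497 for each). It was 0.065 for neural crest with the GC trend removed, and with the trends on GC content, exonic length and genomic span removed it was 0.79 for the respiratory chain, 0.12 for neural crest and 0.32 for ribosomal proteins.

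The combination against osimertinib in HCC827 addresses what 6-thio-dG adds to the EGFR inhibitor. Most changes were small, with a median size of 0.58 on the log2 scale among the genes that passed. ERK pathway output genes fell, 13 of 24 with 0 that rose (median -0.52, adjusted p = 2.8e-06), and 14 of 29 mitosis genes fell with 0 that rose (median -0.66, adjusted p = 3.9e-06). Only 6 mitosis genes fell with the GC trend removed, while the list test still passed (adjusted p = 1.6e-08). DUSP6, a phosphatase that ERK signalling induces, was at -1.29 (adjusted p = 4.5e-06), EGR1 at -0.65 and TOP2A at -1.41 in the authors' deposited table. Genes of translation and respiration rose: 31 of 38 ribosomal protein genes rose and 1 fell (median 0.54, adjusted p = 3.0e-16), all 13 mitochondrially encoded genes rose (median 0.59, adjusted p = 5.7e-09), and 26 of 50 nuclear respiratory chain genes rose and 3 fell (median 0.37, adjusted p = 3.9e-07). RPS15 was at 0.89, MT-ND3 at 0.84 and NDUFA13, a subunit of complex I, at 0.76 in the authors' deposited table, the last of which did not pass with the GC trend removed (adjusted p = 0.058). In this comparison fold change rose with GC content across genes (Spearman's rho 0.73), and the mitochondrially encoded genes, of median GC content 44.3%, rose while the other genes in their GC range had a median of -0.27.

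Other lists passed by less in the HCC827 combination. Of 20 NF-kB genes 6 fell and 1 rose (median -0.61, adjusted p = 0.037), and 6 of 22 YAP and TEAD targets fell with 0 that rose (median -0.15, adjusted p = 0.037). PTGS2, the inducible cyclooxygenase, was at -1.76 and CCN2, a matricellular protein, at -1.29 (adjusted p = 3.8e-09) in the authors' deposited table. Replication-dependent histones had 3 of 10 that rose (median 0.53, adjusted p = 0.021), epithelial genes 9 of 22 that rose and 2 that fell (median 0.24, adjusted p = 0.030), lysosome genes 10 of 30 that rose and 3 that fell (median 0.22, adjusted p = 0.039), glycolysis 9 of 23 that rose and 3 that fell (median 0.22, adjusted p = 0.039) and mesenchymal genes 6 of 14 that rose (median 0.37, adjusted p = 0.047). The keratin KRT7 was at 0.74, the intermediate filament VIM at 0.80 and GAPDH, a glycolytic enzyme, at 0.69 in the authors' deposited table, the last without a call once the GC trend was removed (adjusted p = 0.056). The list tests with that trend removed gave adjusted p = 0.69 for epithelial genes, in the opposite direction, 0.37 for lysosome, 0.67 for glycolysis and 0.12 for mesenchymal genes. NF-kB (0.00012), YAP and TEAD targets (1.2e-05) and histones (0.0012) passed with it removed. With a preset correlation of 0.05 the adjusted p was 0.16 for NF-kB, YAP and TEAD, epithelial and mesenchymal genes, 0.17 for glycolysis, 0.19 for lysosome and 0.066 for histones, and with all 3 trends removed the histones had 0.37.

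The list test did not pass in the HCC827 combination for p53 targets (4 of 27 rose, 5 fell, adjusted p = 0.69), interferon stimulated genes (3 of 32 rose, 9 fell, adjusted p = 0.49), the TCA cycle (5 of 26 rose, 6 fell, adjusted p = 0.53), telomerase and telomere binding (5 of 22 rose, 2 fell, adjusted p = 0.20), homologous recombination and Fanconi genes (0 of 31 rose, 6 fell, median -0.39, adjusted p = 0.067) or DNA replication (0 of 37 rose, 5 fell, median -0.17, adjusted p = 0.27). DNA replication passed with the GC trend removed (adjusted p = 0.0061), downward. Homologous recombination passed on ranks (adjusted p = 0.045), downward too, but not with the GC trend removed (adjusted p = 0.098). With that trend removed 1 gene rose and 0 fell among p53 targets, and likewise among interferon stimulated genes. In the TCA cycle 2 rose and 0 fell. Among telomerase and telomere binding genes 0 rose and 0 fell, as among homologous recombination genes. MDM2, the ligase that degrades p53, was at -0.96 in the authors' deposited table (adjusted p = 0.090 with the GC trend removed). Adjusted over the list alone, 33 ribosomal protein genes and 31 respiratory chain genes rose, and 16 ERK pathway output genes and 15 mitosis genes fell. Readthrough names were among the largest rises here too, with PEDS1-UBE2V1 at 23.87 in the authors' deposited table.

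SUCLG2, which the series title names, encodes the GTP-specific beta subunit of succinyl-CoA ligase, the TCA cycle enzyme that converts succinyl-CoA to succinate. The gene (ENSG00000172340) lies on chromosome 3 from 67360460 to 67654614 on the minus strand of GRCh38, protein coding, with 13 merged exon blocks. It fell in all 4 comparisons as labelled. An exchange of the 6-thio-dG and reference labels in HCC827, which stays open below, would reverse the 6-thio-dG value of that line. The log2 fold change in the authors' deposited table was -1.24 (adjusted p = 4.5e-11) for 6-thio-dG in A375, -1.12 (adjusted p = 1.2e-07) for 6-thio-dG in HCC827, -0.96 (adjusted p = 1.6e-09) for the combination in A375 and -0.65 (adjusted p = 0.00067) for the combination in HCC827. The implied standard errors were 0.180, 0.190, 0.152 and 0.161 in that order. Removing the GC trend gave -1.64, -1.01, -1.16 and -0.24 for SUCLG2, and the last no longer passed (adjusted p = 0.42).

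The other subunits of the enzyme were also measured, and no difference between subunits was tested. SUCLG1, the shared alpha subunit on chromosome 2 (84423523 to 84460045), was at -0.31 (adjusted p = 0.036) for 6-thio-dG in A375 and 0.41 (adjusted p = 0.0037) for the combination in A375 in the authors' deposited table. In HCC827 the authors' deposited table gives SUCLG1 0.15 (adjusted p = 0.60) for 6-thio-dG and 0.31 (adjusted p = 0.069) for the combination. Without the GC trend SUCLG1 was at -0.80 (adjusted p = 1.3e-08) for 6-thio-dG in A375. Its combination values were then 0.19 in A375, which did not pass (adjusted p = 0.19), and 0.77 in HCC827, which did (adjusted p = 4.1e-06). SUCLA2, the ATP-specific beta subunit on chromosome 13 (47745736 to 48037968), was at -0.83 (adjusted p = 0.0029) for the combination in HCC827 in the authors' deposited table, and this too did not pass with the GC trend removed (adjusted p = 0.33). Its other values there, in the authors' deposited table, were 0.35 and 0.20 in A375 and -0.19 for 6-thio-dG in HCC827, none of which passed, although 0.55 for the A375 combination with all 3 trends removed did (adjusted p = 0.0023). As deposited, none of 4 tests of a difference between comparisons passed for SUCLG2. HCC827 minus A375 was 0.11 (adjusted p = 0.74) for 6-thio-dG and 0.31 (adjusted p = 0.22) for the combination. The combination effect minus the 6-thio-dG effect was 0.28 (adjusted p = 0.33) in A375 and 0.48 (adjusted p = 0.16) in HCC827. After removal of the GC trend 3 of these passed, at 0.63 (adjusted p = 0.036), 0.92 (adjusted p = 0.00015) and, in HCC827, 0.77 (adjusted p = 0.017). In A375 0.47 did not (adjusted p = 0.082). After removal of all 3 trends they were 0.84 (adjusted p = 0.0042), 0.75 (adjusted p = 0.0025), 0.73 (adjusted p = 0.0056) and 0.64 (adjusted p = 0.056). Whether the fall of SUCLG2 differs between comparisons thus depends on the trend correction.

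**Figure D3:**
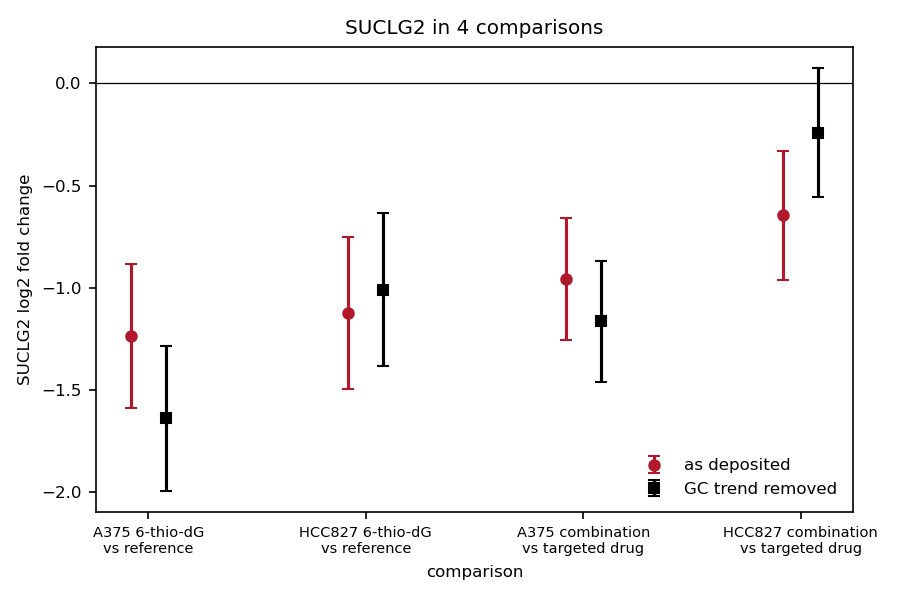
SUCLG2 log2 fold change (vertical axis) in the 4 comparisons (horizontal axis) as deposited and with the GC trend removed; bars are 95% intervals from the implied standard errors. The HCC827 combination went from -0.65 to -0.24.

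SUCLG2 was 1 of 54 genes that fell in all 4 comparisons, against 30.1 if the comparisons were independent, and 37 genes rose in all 4, against 29.6. The comparisons within a line were not independent. Genes that fell in both numbered 1995 against 1168 by chance in A375 and 483 against 305 in HCC827. Genes that rose in both numbered 1814 against 1155 and 467 against 303. The numbers expected for all 4, with or without the GC trend, leave out this sharing, so no excess can be read from them. The 54 included ANO1, a chloride channel, MUC5B, CXCL1 and DPYD, a pyrimidine-degrading enzyme. They ranked ahead of SUCLG2, which was number 9 by the smallest of its 4 falls and number 26 by its mean log2 fold change. The genes that rose included CLU, an extracellular chaperone, HSPB8, a small heat shock protein, and CDA, cytidine deaminase. ANO1, DPYD, CLU, HSPB8 and CDA lie outside the naming rule and were chosen after their values were seen. The median genomic span was 101986 bp for the fallen genes and 11909 bp for the risen ones against 32753 bp for all genes, and the median GC content was 43.6%, 57.8% and 48.4%. Removal of the GC trend left 23 genes that fell in all 4, against 4.73 if independent, and 11 that rose, against 6.85, and SUCLG2 was not among them.

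The response to 6-thio-dG differed between the lines at 6513 of 11821 genes tested, and 1357 of these 6513 also passed in both lines with opposite signs. Among the lists tested, cell-cycle lists had the largest median differences: HCC827 minus A375 had a median of 4.00 for mitosis (adjusted p = 3.3e-48) and 3.54 for DNA replication (adjusted p = 3.1e-62), with 25 and 36 genes higher in HCC827. MCM5 was at 1.06 in HCC827 and -3.97 in A375, and CDC20 at 1.19 and -4.46, in the authors' deposited table. The p53 targets had a median difference of -1.48 (adjusted p = 7.3e-12), with GADD45A at -1.47 in HCC827 and 3.45 in A375 in the authors' deposited table. Of the genes that fell in A375, 822 rose in HCC827 against 589 by chance (odds ratio 1.94, Fisher's exact adjusted p = 1.9e-35), whereas 393 rose in both against 548 by chance (odds ratio 0.592, adjusted p = 1.2e-18). The number that fell in both, 572, lay near the 574 by chance (odds ratio 0.992, adjusted p = 0.91). With the GC trend removed the odds ratio for genes that fell in both was 1.27, and that for genes that rose in both, 0.909, did not pass.

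**Figure D4:**
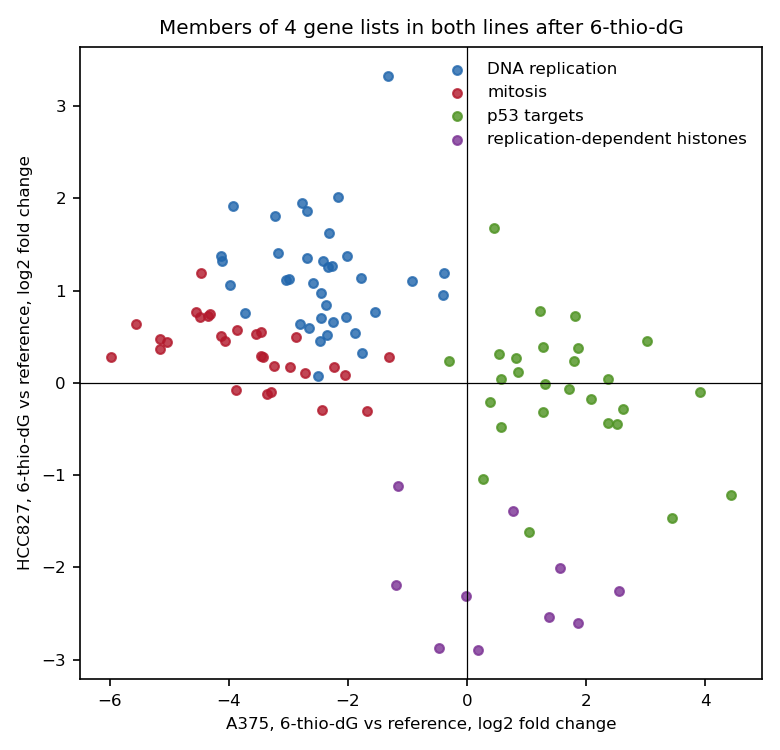
Log2 fold change after 6-thio-dG in A375 (horizontal axis) and HCC827 (vertical axis), 1 point per gene of 4 lists. All 37 DNA replication genes lie below 0 in A375, and 34 of them rose in HCC827.

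The combination effect differed between the lines at 6673 of 11812 genes tested. HCC827 minus A375 was higher for antigen presentation (median 2.07, adjusted p = 6.7e-16), interferon stimulated genes (median 1.86, adjusted p = 6.3e-11) and mesenchymal genes (median 1.90, adjusted p = 1.1e-10), and lower for p53 targets (median -1.26, adjusted p = 2.3e-07) and ATF4 and unfolded protein response genes (median -0.90, adjusted p = 2.3e-07). BST2 was at 0.21 in HCC827 and -4.51 in A375, and DDIT3 at 0.02 and 5.03, in the authors' deposited table. The mitochondrially encoded genes had a median difference of 1.23 (adjusted p = 2.4e-06). Genes that rose in both lines numbered 558 against 639 by chance (odds ratio 0.794, adjusted p = 2.3e-05), and genes that fell in both 539 against 620 (odds ratio 0.792, adjusted p = 2.3e-05). With the GC trend removed both turned, to odds ratios of 2.01 and 1.77, so the direction of this overlap depended on that step.

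Whether 6-thio-dG did the same with and without the targeted drug was tested as the combination effect minus the 6-thio-dG effect. In A375 6205 of 11805 genes tested departed from additivity, and in HCC827 2636 of 11828. Within A375 the genes that rose in both comparisons numbered 1814 against 1155 by chance (odds ratio 3.20, adjusted p = 7.4e-169), and those that fell in both 1995 against 1168 (odds ratio 4.34, adjusted p = 2.8e-264). The difference in A375 was positive for DNA replication (median 2.18, adjusted p = 2.6e-24) and mitosis (median 2.01, adjusted p = 4.4e-09) and negative for interferon stimulated genes (median -2.53, adjusted p = 2.8e-12) and antigen presentation (median -1.36, adjusted p = 1.6e-09). MCM7, a subunit of the replicative helicase, was at 0.24 with PLX4720 and -2.58 without it, and IFI6 at -2.51 and 0.90, in the authors' deposited table. No comparison of the targeted drug with the control was available. Whether such genes had already moved under PLX4720 alone is therefore unknown. In HCC827 the difference was negative for DNA replication (median -1.17, adjusted p = 1.7e-23) and mitosis (median -1.21, adjusted p = 2.9e-11), and positive for replication-dependent histones (median 2.78, adjusted p = 5.7e-20), mitochondrially encoded genes (median 1.70, adjusted p = 5.3e-22), ribosomal proteins (median 0.68, adjusted p = 1.0e-11) and antigen presentation (median 0.77, adjusted p = 3.8e-12). CD74 was at 0.02 with osimertinib and -3.69 without it, and MT-ND4 at 0.59 and -1.47, in the authors' deposited table. These HCC827 differences take the 6-thio-dG and reference labels as given, and an exchange of them stays open below. Genes that rose in both HCC827 comparisons numbered 467 against 303 by chance (odds ratio 1.95, adjusted p = 3.3e-26), which did not pass with the GC trend removed (odds ratio 1.04). Those that fell in both numbered 483 against 305 (odds ratio 2.05, adjusted p = 1.7e-30), and this passed with that trend removed (odds ratio 2.36, adjusted p = 4.5e-11).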

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

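The tests of GC content and of exchanged labels for the DNA replication genes were chosen only after the result was seen. The results in this part stand out because the same contrast gave different effects in A375 and HCC827, by a test of the difference itself. In the combination the targeted drug also differed between the lines (PLX4720 in A375, osimertinib in HCC827), so that difference carries the drug as well as the line. For 6-thio-dG, 6513 genes differed between the lines. The median difference, HCC827 minus A375, was 4.00 for mitosis, 3.54 for DNA replication, 1.98 for homologous recombination and Fanconi genes, 1.06 for glycolysis and 0.79 for cholesterol biosynthesis. It was -1.48 for p53 targets, -0.97 for NF-kB and inflammatory cytokines, -0.99 for ATF4 and unfolded protein response genes and -2.74 for replication-dependent histones.

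For the combination against the targeted drug, 6673 genes differed between the lines. The median difference, HCC827 minus A375, was 0.75 for mitosis, 1.23 for mitochondrially encoded genes, 1.86 for interferon stimulated genes, 2.07 for antigen presentation, 0.48 for NF-kB and inflammatory cytokines, 1.90 for mesenchymal genes, 0.58 for lysosome genes and 2.44 for replication-dependent histones. It was -1.26 for p53 targets, -1.02 for antioxidant and ferroptosis genes, -0.90 for ATF4 and unfolded protein response genes and -0.67 for the mitochondrial unfolded protein response and biogenesis. A preset correlation of 0.05 ended the calls of mitosis (adjusted p = 0.12), NF-kB (0.14) and lysosome (0.12) for the combination and of cholesterol biosynthesis (0.18) for 6-thio-dG, and ranks ended that of ATF4 for 6-thio-dG (0.070). Removing the GC trend ended those of NF-kB (0.078) and lysosome (0.080) for the combination, and removing all 3 trends that of cholesterol biosynthesis (0.055) for 6-thio-dG.

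DNA replication genes fell in A375 and rose in HCC827 after 6-thio-dG, and the trend on GC content is not the whole cause, because with it removed the median difference between the lines was 3.49 (95% bootstrap interval 3.04 to 3.80). Exchanged labels of the 6-thio-dG and reference libraries in HCC827 cannot be told apart from a response. With the GC trend removed 62.5% of the 283 genes called in both HCC827 comparisons had the same sign (95% binomial interval 56.8% to 68.0%), against such an exchange. As deposited, with a GC trend that rose in both comparisons, 74.7% of 1272 such genes had the same sign. Of the 37 DNA replication genes only 35.1% did with that trend removed (21.8% to 51.2%). These genes raised the question, and only 5 of them were called in the combination. Genes are not independent, so these intervals are likely too narrow. Of 6 lists called in both HCC827 comparisons, medians had opposite signs in 3, as an exchange would give, for mitosis (0.36 with 6-thio-dG, -0.66 in the combination), histones (-2.28, 0.53) and mitochondrially encoded genes (-1.09, 0.59), and the same sign in 3, NF-kB (-1.28, -0.61), ERK pathway output (-0.33, -0.52) and glycolysis (0.17, 0.22). Over all 31 lists tested 12 had the same sign and 19 opposite signs, DNA replication (1.11, -0.17) among the latter, although the drug present differs between these comparisons. With the GC trend removed 5 of 9 lists called in both had the same sign. Opposite medians also occurred in A375, for example for interferon stimulated genes (0.36 with 6-thio-dG, -1.99 in the combination). Every list called in both A375 comparisons kept its sign, however. Over all genes with the GC trend removed, 63.3% had the same sign in the A375 comparisons and 54.2% in HCC827. Opposite list medians alone therefore do not mark an exchange. A difference in how the lines respond stays open as well, untested, as do their tissue, driver mutation and culture history and, without values per library, a library that stands apart from its pair.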

How the results depend on the processing

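All alternatives in this part were chosen after the data were seen; the planned ones (another normalisation, another low-count filter, another tool, leaving out a library, a replicate block) need values per library and were not run. No paired analysis was possible because the table holds comparisons without values per library. Depth is unknown, so what it limits could not be assessed. Except where the construction is named, the cause was not tested.

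Recomputing the adjustment over the table's genes, or reading the p-value as a t test with 4 degrees of freedom, kept the counts tried under each within 1.5 times, although the t reading gives genes with very small p-values standard errors near 0. Stricter thresholds lowered counts by construction. At an adjusted p of 0.01, genes called numbered 2239 for HCC827 6-thio-dG vs reference, 2586 for HCC827 combination vs targeted drug and 1559 for HCC827 departure from additivity, with 16 genes that fell in all 4 comparisons and 10 that rose. At 2-fold or more, genes called numbered 3668 for A375 6-thio-dG, 998 for HCC827 6-thio-dG, 3202 for A375 combination, 273 for HCC827 combination, 3454 for A375 departure from additivity, 1262 for HCC827 departure from additivity and 4021 for the combination effect HCC827 minus A375. Removing the GC trend left 910 genes called for the HCC827 combination, with 23 that fell and 11 that rose in all 4 comparisons. With the GC, exonic length and span trends removed these were 722, 16 and 4.

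Overlaps between the lines depended on the alternative. For 6-thio-dG, the odds ratio for genes that rose in both was 0.884 at 2-fold and 0.909 with the GC trend removed, no longer passing; for genes that fell in both it was 1.27 with the GC trend removed and 1.21 with all 3 trends removed, now passing. For genes that rose in A375 and fell in HCC827 it was 1.85 at 2-fold (1.02 as deposited, not passing), 0.819 with the GC trend removed and 0.871 with all 3 removed. For the combination it reversed to 1.40 (3 shared genes, adjusted p = 0.65, not passing), 2.01 and 1.31 for genes that rose in both and to 1.55, 1.77 and 1.74 for genes that fell in both, in the same order. For genes that rose in A375 and fell in HCC827 it was 0.860 as deposited, 0.921 at 2-fold and 0.780 with all 3 removed, the last 2 not passing. For the opposite pair it was 1.47 as deposited, 1.04 at 2-fold, and reversed to 0.557 and 0.905 with the GC trend and with all 3 removed; 1.04 and 0.905 did not pass. Within HCC827, genes that rose in both gave 1.31 at 2-fold, 1.04 with the GC trend removed and, reversed, 0.894 with all 3 removed, none of which passed. Genes that rose with 6-thio-dG and fell in the combination gave 0.372 as deposited, 0.762 at 2-fold, reversed to 1.08 and 1.15 under the trends, the last 3 not passing. The opposite pair, 0.509 as deposited, reversed to 4.13 at 2-fold (3 shared genes, adjusted p = 0.085) and gave 0.861 with all 3 removed, neither passing. The 4 overlaps within A375 kept their direction and passed under these alternatives.

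SUCLG2 in the HCC827 combination was at -0.24 with the GC trend removed and -0.21 with all 3 removed, past no threshold, and it passed in the other 3 comparisons under both. No difference of SUCLG2 between comparisons passed as deposited. The 6-thio-dG effect HCC827 minus A375, A375 departure, HCC827 departure and combination effect HCC827 minus A375 were 0.11, 0.28, 0.48 and 0.31, and all passed under the t reading, by its construction. With the GC trend removed 0.63, 0.77 and 0.92 passed, in that order without the A375 departure. With all 3 removed 0.84, 0.73 and 0.75 passed, in that order without the HCC827 departure. Named genes that reversed there were DLD (0.032 and 0.00010), H2BC12 (-0.35, all 3 trends) and MUC1 (-0.0039, GC trend). The epithelial list test there reversed, with adjusted p = 0.69 and 0.66. Of the named-gene results 265 kept their call status with the GC trend removed, 40 lost the call, 1 gained it and 2 called results reversed direction. Of the list tests 222 kept their call status, 10 lost the call, 15 gained it and 1 called result reversed, and a preset correlation of 0.05 ended 27 calls. A result without a call before and after counted as kept even where its direction changed, such as ribosomal proteins for 6-thio-dG in A375.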

Other observations

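The tests of SUCLG2 in the HCC827 combination alone and of the GC trend were chosen only after the result was seen. Replication-dependent histones and DNA replication genes, which are usually used in the same phase of the cell cycle, moved apart in HCC827 after 6-thio-dG: 8 of 10 histones fell (median -2.28) while 34 of 37 DNA replication genes rose (median 1.11). In A375 after 6-thio-dG 4 of the 10 histones rose and 1 fell (median 0.48, list adjusted p = 0.33) while all 37 DNA replication genes fell. The libraries were selected for a poly(A) tail, which most transcripts of these histone genes lack. The histone values may therefore not follow their total transcripts, and a divergence within a cell-cycle phase cannot be read from them. The mitochondrially encoded genes had medians of -0.57 (list adjusted p = 0.072) and -0.66 (0.021) in the A375 comparisons and of -1.09 and 0.59 in HCC827. In A375 after 6-thio-dG 10 of 13 of them fell and 1 rose. That list test passed with the GC trend removed (adjusted p = 0.0070) and on ranks (0.017), but not with a preset correlation of 0.05 (0.19). Markers of another epithelial type were also counted: of 6 squamous and basal keratins 3 rose in A375 after 6-thio-dG and 1 rose in HCC827, with list adjusted p = 0.28 and 0.60.

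Cholesterol biosynthesis passed the list test in none of the 4 comparisons, except on ranks for 6-thio-dG in HCC827 (adjusted p = 0.026, upward). In A375 the combination effect minus the 6-thio-dG effect had a median of 0.94 (adjusted p = 0.00042), with 16 of 24 genes higher and 2 lower. Purine analogue handling also departed from additivity in A375 (median 0.46, adjusted p = 0.0022), with PNP, purine nucleoside phosphorylase, at 2.26 and 0.11 in the authors' deposited table.

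SUCLG2 fell in all 4 comparisons. No single gene property accounts for this as a whole: the median of the 200 genes nearest in genomic span reached 0.204 in A375 after 6-thio-dG, of those nearest in exonic length 0.161 in the A375 combination, and of those nearest in GC content 0.359 in A375 after 6-thio-dG. That test asked a property to account for all 4 comparisons, so a single comparison could fail it, and GC trends ran in opposite directions in A375 and HCC827. Genes nearest in span had medians of -0.242 for 6-thio-dG in HCC827, -0.228 for the combination in A375 and -0.315 for that in HCC827. SUCLG2 stood at percentiles 5.5, 24 and 22.5 among them, in that order. In the HCC827 combination alone the GC trend is a candidate explanation, since the 200 genes nearest in GC content had a median of -0.41 (95% interval -0.50 to -0.35) and SUCLG2 went from -0.65 (implied standard error 0.161) to -0.24 with the trend removed; the call ended because the value shrank. Long span could not be excluded there either, with a median of -0.315 among the 200 genes nearest in span. A fall of SUCLG2 caused by 6-thio-dG in the other 3 comparisons may be taken as a hypothesis only, because a property of the libraries could not be tested without values per library. For 6-thio-dG in HCC827 the fall (-1.12) also rests on the labels, since an exchange of them, which stays open, would make it a rise.

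Fold change rose with GC content in the HCC827 combination. Exonic length is argued against as the source of this GC trend, since the partial correlation with GC content was 0.675 with exonic length and span held constant. GC content was not the only trend. With it removed, Spearman's rho across genes was still -0.229 with exonic length and -0.224 with span, from -0.353 and -0.433 as deposited. A GC bias between libraries is consistent with the trend appearing inside functional groups: the median within-list correlation was 0.687 over 22 lists, all above 0 (0.417 to 0.909). A response of the cells that follows GC content would also appear inside lists and stays open, as it needs values per library to separate.

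Because 6-thio-dG acts at telomeres, genes near chromosome ends were hypothesised to move together. Genes within 5 Mb of the first or last annotated gene of a chromosome (1607 genes) were compared with 10175 others, with span and GC content regressed out. The first annotated gene can lie far from the physical end, as on chromosome 13, so some of these genes may not be near a telomere. The median difference farthest from 0 was -0.107 (95% bootstrap interval -0.155 to -0.062) in A375 after 6-thio-dG, and in the other 3 comparisons it was -0.021, -0.016 and 0.0045, so a shared effect of more than 0.1 was not seen. Before the regression the differences were -0.43, 0.09, -0.28 and 0.30.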
